A study of Mus musculus with 24 samples.

How the data were processed

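RNA sequencing was run on ribosome-depleted total RNA from neuron-enriched cortical cultures of newborn male mice, wild-type or Mecp2-null and from the same litters, untreated or exposed to 35 mM KCl for 3 h after 10 days in culture. The deposited table for these cultures holds counts, made by the authors, as whole numbers for 31489 gene names in 12 libraries. STAR, DESeq2 and DESeq and the genome build mm10 (GRCm38) are named per the submitters' processing notes. Their roles, versions and settings, the counting tool, the gene annotation and the strand setting are not given in the sources used here. The strand being unknown, counts of genes that overlap another gene on the opposite strand are uncertain, and so are those of near-identical genes such as the histone genes and the pair Hspa1a and Hspa1b. Gene names turned into dates, 26 in all, were tested but not named.

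Each library was assigned to its group by genotype and treatment in its column name, which gave 4 groups of 3 libraries. The labels number 3 experiments, but the column names carry other numbers that appear in no label, so no library was tied to an experiment and no block for the labels' experiments was fitted. A deposited table for the hippocampus of mice given kainic acid, an agonist of glutamate receptors that induces seizures, also holds whole numbers. Its 12 columns of per-sample values were not used, because their names appear in no sample label. The 11 planned hippocampus comparisons were therefore not run.

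Expression was compared with edgeR 4.0.16 in R 4.3.3. Counts were scaled by the TMM method, genes with low counts were removed by filterByExpr, and 19972 genes were tested by quasi-likelihood F-tests in 1 fit of 4 groups. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. Adjusted p values in the text come from edgeR for genes and from camera for gene lists, and 6 comparisons were tested. Fold changes are given on the log2 scale with their standard error (SE), which was derived from the fold change and its F statistic. Levels are counts per 1e6 total counts (CPM) after TMM scaling, given with the standard deviation (SD). Total counts per library ran from 40.8 to 50.4 in units of 1e6.

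The 34 gene lists were fixed before the data were examined, as were the comparisons, tests and rules for naming genes. They were tested with camera in limma 3.58.1 on voom values, with a preset correlation of 0.01 between genes and again with the correlation estimated for each list, adjusted over the lists of a comparison. Members that rose or fell are counted over all genes tested and, where stated, adjusted over the list alone. Genes over 100 kb were tested as a further class in the genotype comparisons. Gene lengths and positions came from the GENCODE mouse annotation, release 21, on GRCm38. Of the gene names, 29860 were matched by symbol and 390 by a synonym, and 97.4% of the tested genes had a length.

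Per library, 3 scores were computed. The KCl response score is the mean log2 CPM of genes induced minus that of genes reduced in the response averaged over genotypes. The long gene score is the median log2 CPM of genes over 100 kb minus that of shorter genes. The early gene score, added after the data were examined, is the mean log2 CPM of the rapid immediate early genes. Genotype differences in scores were tested by exact two-sided permutation of genotype labels within treatments.

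Named genes were Mecp2, Irak1, Bdnf, Fos, Arc, Npas4 and Egr1 in any comparison. To these were added up to 6 genes that rose and 6 that fell with the largest fold changes among called genes with a mean of at least 2 CPM in the higher group and no overlap between libraries, without predicted genes. Up to 4 called members with the largest fold changes were named for each list, or, where none was called, the members of lowest p. Where no gene of a comparison was called, the 5 genes of lowest p were given as values.

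Alternatives were DESeq2 1.42.0, DESeq2 size factors in edgeR, no filter on low counts, a fit of only the groups compared, leaving out each library in turn, and other limits for the scores. After the data were examined, a fit with library set as a term, a fit of the high-numbered libraries only, a fit of the KCl responses with pairs of libraries as a block, a fit of the genotypes with the counts of each pair summed and permutations within library sets and of whole pairs were added. A pair is an untreated and a KCl library of a genotype whose column numbers follow each other, such as WT1_N and WT2-WT3_T. Library set parts the 4 libraries with low numbers in their column names from the 8 with high numbers. The models were tested on simulated data drawn from the fit with library set as a term, in which 50 genes were changed at each of 4 known folds.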

Results

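Gene expression was measured by RNA sequencing in cortical cultures enriched for neurons, made from newborn male mice that carried or lacked Mecp2. Mecp2 is an X-linked gene that encodes a protein binding methylated DNA, and its mutation causes Rett syndrome in humans. Cultures were left untreated or depolarised with 35 mM KCl for 3 h, which opens voltage-gated calcium channels and induces activity-dependent genes. The 4 groups were wild-type untreated, wild-type with KCl, Mecp2-null untreated and Mecp2-null with KCl, with 3 libraries in each. Total counts, in units of 1e6, were 43.9, 40.9 and 49.2 in wild-type untreated libraries and 41.7, 40.8 and 45.4 in wild-type KCl libraries. In Mecp2-null libraries they were 47.2, 50.4 and 44.0 untreated and 46.9, 41.4 and 42.4 with KCl. The series also holds 12 hippocampus samples, whose columns could not be tied to samples. The labels do not tie a library to a numbered experiment or to animals, so each p measures the spread between these libraries.

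Genes of the interferon response, of astrocytes, of microglia, of fibroblasts and of dividing cells stood far higher in 4 of the 12 libraries, and many neuronal genes stood lower there. These 4 libraries, 1 in each group, carry numbers of at most 3 in their names and are called low-numbered, and the other 8 carry numbers from 27 to 47 and are called high-numbered. The set was defined after the data were examined, and no label names it. The labels number 3 experiments, each with 1 sample of every group, as the low-numbered libraries have. Whether these libraries are 1 of those experiments cannot be told from the labels. Oasl2, an antiviral gene induced by interferon, averaged 58.2 ± 9.05 CPM (SD, n = 4) in low-numbered and 1.18 ± 0.147 CPM (SD, n = 8) in high-numbered libraries. Vim, an intermediate filament gene of glia and progenitors, averaged 1613 ± 414 CPM (SD, n = 4) against 181 ± 21.2 CPM (SD, n = 8).

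In an edgeR fit with library set as a term, 6869 genes were higher and 6608 lower in low-numbered libraries, of 19972 tested. All 18 measured interferon-response genes rose, over all genes and adjusted over the list alone, with a median log2 difference of 4.88. Their camera adjusted p was 4.03e-12, and adjusted p = 0.303 with an estimated correlation. Of 17 microglia markers 16 rose and 1 fell, also adjusted over the list alone, with a median of 2.92, Trem2 at 6.27 and C1qa at 4.62. The microglia list was the only one of the 34 to pass in this comparison with an estimated correlation (adjusted p = 0.0418). The astrocyte list had 14 of 16 members higher, among them Aqp4 by 2.91 and Gfap by 2.61 (camera adjusted p = 2.07e-06, and adjusted p = 0.373 with an estimated correlation). Of 10 oligodendrocyte markers 5 rose and 3 fell, and the list did not pass (camera adjusted p = 0.429). Of the fibroblast and meningeal markers 12 of 13 rose, with Lum at 6.80 (camera adjusted p = 9.12e-05, and adjusted p = 0.518 with an estimated correlation). Of the proliferating and progenitor cell markers 19 of 20 rose, with Mki67 at 2.96 (camera adjusted p = 2.56e-10, and adjusted p = 0.373 with an estimated correlation), and 39 of 40 replication-dependent histone genes rose (adjusted p = 0.41 with an estimated correlation).

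Lower in low-numbered libraries were all 23 genes of cholesterol synthesis, with Lss, which makes lanosterol, at -1.75 and Fdps at -1.50 (camera adjusted p = 5.52e-12, and adjusted p = 0.458 with an estimated correlation). The voltage-gated sodium and calcium channels fell in 24 of 26 members, the ionotropic glutamate receptors in 15 of 17 and the excitatory neuron markers in 11 of 15, each with adjusted p = 0.518 with an estimated correlation. Among them were Scn1a at -1.07, Gria2 at -0.95 and Neurod1 at -1.47. Of the choroid plexus markers 10 of 13 rose and 3 fell, with Ttr, a transthyretin gene, at 9.68 (adjusted p = 0.518 with an estimated correlation). The first principal component of the 1000 most variable genes held 83.6% of their variance and parted the sets, and the second held 11.9% and parted KCl from untreated libraries.

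**Figure D1:**
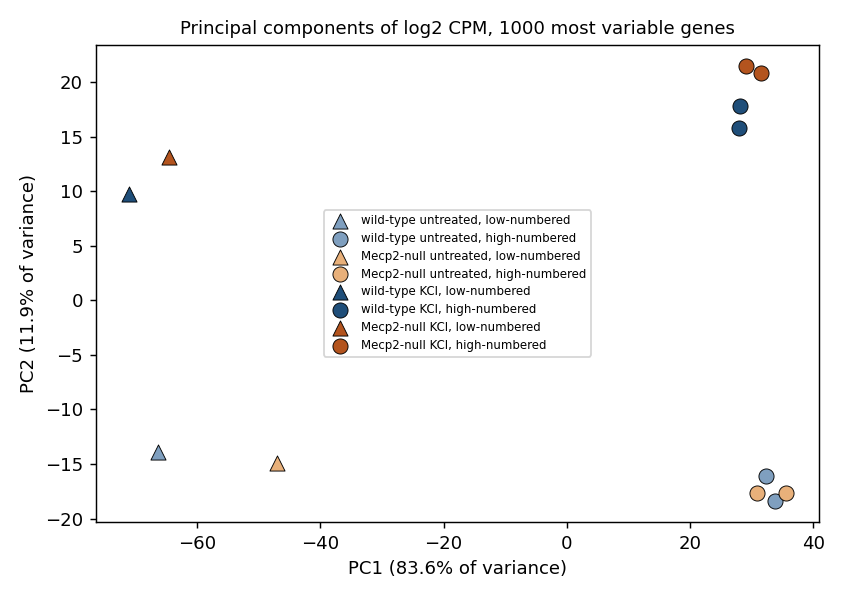
First and second principal components of log2 CPM of the 1000 most variable genes, with 1 point per library, triangles for low-numbered and circles for high-numbered libraries and colours for the 4 groups. The first component (83.6% of variance) separates the library sets and the second (11.9%) the treatments.

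Mecp2 itself (X chromosome, 74026592 to 74135363 on GRCm38) served as the check of genotype. It averaged 200.5 ± 22.3 CPM (SD, n = 3) in wild-type untreated and 169 ± 22.3 CPM (SD, n = 3) in wild-type KCl libraries. In Mecp2-null libraries it averaged 12.2 ± 3.23 CPM (SD, n = 3) untreated and 8.54 ± 0.951 CPM (SD, n = 3) with KCl. The lowest wild-type library held 143.6 CPM and the highest Mecp2-null library 15.2 CPM. Irak1, the neighbouring gene (74013914 to 74023918 on the X chromosome), which encodes a kinase of innate immune signalling, was higher in every Mecp2-null library than in every wild-type library. Irak1 ranged from 40.0 to 47.7 CPM in Mecp2-null libraries. In wild-type libraries Irak1 stood at 34.9 and 33.7 CPM in the low-numbered and from 11.9 to 13.9 CPM in the high-numbered libraries.

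**Figure D2:**
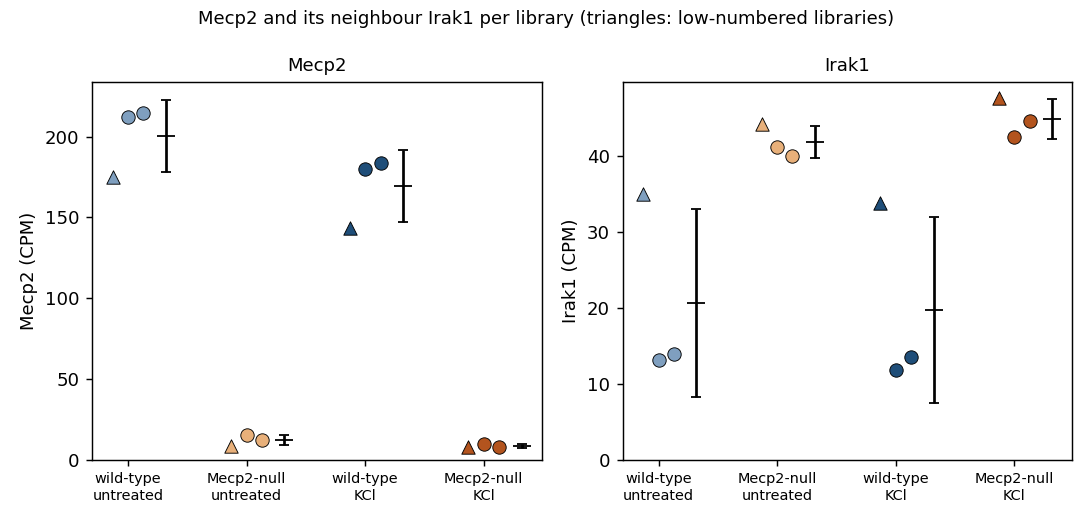
CPM of Mecp2 (left) and of Irak1 (right) in each of the 12 libraries by group, triangles for low-numbered and circles for high-numbered libraries, with a bar for the mean and SD of the 3 libraries of a group. Mecp2 was at most 15.2 CPM in Mecp2-null libraries, and Irak1 in the 2 low-numbered wild-type libraries lay above the 4 high-numbered wild-type libraries.

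The response of wild-type cultures to KCl shows which genes depolarisation changes when MeCP2 is present. Among the genes with the largest rises were transcription factors of the immediate early response. Fos (chromosome 12, 85473890 to 85477273) went from 18.6 ± 5.12 to 542 ± 128.5 CPM (SD, n = 3 each), a log2 fold change of 4.87 (SE 0.28, adjusted p = 0.000159). Npas4 (chromosome 19, 4984355 to 4990316), a neuronal factor induced by calcium entry, rose by 4.80 (SE 0.40, adjusted p = 0.000796), Fosb by 5.40 and Atf3 by 4.94. Bdnf, a neurotrophin gene, rose by 2.69 (SE 0.62, adjusted p = 0.0411), a call that was lost when any of 5 of the 6 wild-type libraries was left out.

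For the KCl response in wild-type cultures, edgeR called 380 genes higher and 521 lower of 19972. With DESeq2 size factors in edgeR the split was 365 higher and 311 lower. Other genes with large rises were Areg, a ligand of the EGF receptor, at 4.81 and Nr4a2, an orphan nuclear receptor gene, at 4.24. The largest falls were those of Ankrd63 at -3.44 (SE 0.51), Zkscan16 at -2.42 and the kinase gene Dclk3 at -2.18, followed by Cecr6 at -1.83, Zfp94 at -1.79 and Gpr45 at -1.77, where the call of Zfp94 was lost without any of the 4 high-numbered libraries. The count was 123 to 241 when any of the 4 high-numbered wild-type libraries was left out, 1022 and 1355 without a low-numbered library, 454 with no filter, 4513 with library set as a term, 6464 in high-numbered libraries only and 5369 with untreated and KCl libraries paired by neighbouring column numbers, a pairing the labels do not give. It was 1 when only the 6 wild-type libraries were fitted, and DESeq2 called 1690.

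Among the rapid immediate early genes, 19 of 27 rose in wild-type cultures, none fell and 8 did not pass, and 23 rose when adjusted over the list alone. Their median was 2.13 (camera adjusted p = 5.64e-38, and adjusted p = 0.00109 with an estimated correlation). With an estimated correlation adjusted p was 0.0481 with library set as a term, 0.567 in high-numbered libraries only and 0.529 with libraries paired, while the median stood at 2.31, 2.87 and 2.31 in these fits. Arc, a synaptic plasticity gene, rose by 1.51 and Egr1, a zinc finger factor, by 1.14. Of 39 delayed and secondary activity response genes 22 rose and none fell, 33 when adjusted over the list alone (camera adjusted p = 1.07e-30, and adjusted p = 0.0722 with an estimated correlation). Among them Ptgs2, the inducible cyclooxygenase, rose by 4.02 (SE 0.26), Nr4a3 by 2.89 and Pcsk1, a prohormone convertase, by 2.78. Of 16 MAP kinase feedback regulators 7 rose and 1 fell, 10 and 2 when adjusted over the list alone (camera adjusted p = 1.41e-08, and adjusted p = 0.0722 with an estimated correlation). Dusp1, a phosphatase also on the early gene list, rose by 2.70, Errfi1 by 2.10 and Dusp4 by 1.79.

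Smaller shifts were seen in stress and hormone lists with KCl in wild-type cultures. Of 17 heat shock and chaperone genes 4 rose and 1 fell, the same numbers when adjusted over the list alone (camera adjusted p = 0.00379, and adjusted p = 0.238 with an estimated correlation). Hspa1b rose by 2.08, Dnajb4 by 1.58 and Hspa1a by 0.94. Of 19 unfolded protein response genes 2 rose, Herpud1 by 0.73 and Dnajb9 by 0.55, and 5 when adjusted over the list alone (camera adjusted p = 0.000164, and adjusted p = 0.0899 with an estimated correlation). Of 19 glucocorticoid responsive genes 5 rose and 1 fell, 6 and 1 when adjusted over the list alone (camera adjusted p = 0.000136, and adjusted p = 0.141 with an estimated correlation). The members that moved most were Dusp1, Per1 at 2.24, Errfi1 and Sgk1 at 1.21, of which Dusp1 and Errfi1 also stand on the MAP kinase list. In the cytokine and NF-kB list 3 of 13 rose, Il1a by 3.79, Csrnp1 by 3.01 and Nfkbiz by 1.10, 4 when adjusted over the list alone (camera adjusted p = 0.0236, and adjusted p = 0.965 with an estimated correlation).

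Genes of the sex chromosomes included the Y-linked Ddx3y, an RNA helicase gene, which rose with KCl by 1.73 (SE 0.30), and Uty, a histone demethylase gene, by 0.91 (SE 0.17) in wild-type cultures. These were the 2 of 6 listed genes to rise, also adjusted over the list alone (camera adjusted p = 0.0283, and adjusted p = 0.261 with an estimated correlation). The other 26 lists did not pass in wild-type cultures in the fit of all libraries. With libraries paired, potassium channels (camera adjusted p = 0.00338) and sodium and calcium channels (0.0474) passed downward and histone genes upward (0.0474). Cholesterol synthesis passed upward with library set as a term (camera adjusted p = 0.0258). None of these passed with an estimated correlation. Of 27 voltage-gated potassium channels 2 fell, Kcna2 by 1.15 and Kcnb1 by 0.67, and 1 rose and 3 fell when adjusted over the list alone (camera adjusted p = 0.108). Of 56 splicing regulators 2 rose and 2 fell, with Mbnl2 at 0.97, Tra2a at 0.50, Tia1 at -0.59 and Srsf4 at -0.50 (camera adjusted p = 0.423). Of 34 genes often linked to MeCP2 3 rose, Bdnf, Sgk1 and Sst, the last by 0.95, and 2 fell, 5 and 2 when adjusted over the list alone (camera adjusted p = 0.259). Prox1, a dentate granule cell marker, rose by 1.32, the only one of its 10 listed genes (camera adjusted p = 0.259). No listed marker of astrocytes, microglia or fibroblasts passed with KCl in the fit of all libraries in wild-type cultures, while 1 microglia marker rose with library set as a term, and 2 astrocyte markers and 1 microglia marker in high-numbered libraries only.

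Mecp2-null cultures were treated alike, which shows the response in the absence of MeCP2. Fos rose from 15.4 ± 1.83 to 697 ± 131.3 CPM (SD, n = 3 each), a log2 fold change of 5.50 (SE 0.29, adjusted p = 6.74e-05). Fosb rose by 6.06, Atf3 by 5.73, Areg by 5.45, Npas4 by 5.38 (SE 0.41, adjusted p = 0.000314), Serpinb2, a protease inhibitor gene, by 5.23 and Bdnf by 3.03. As in wild-type cultures, the call of Bdnf was lost without any of 5 of the 6 libraries and that of Zfp94 without any of the 4 high-numbered libraries. Ankrd63 fell by 3.67, and further falls were Zkscan16 at -2.53, Dclk3 at -2.48, Cecr6 at -2.10, Zfp94 at -2.02 and Zfp354b at -2.02. For the KCl response in Mecp2-null cultures, edgeR called 645 genes higher and 862 lower, and 681 higher and 602 lower with DESeq2 size factors. The count was 454 to 505 when any of the 4 high-numbered Mecp2-null libraries was left out, 1062 and 1913 without a low-numbered library, 5378 with library set as a term, 7133 in high-numbered libraries only, 6380 with libraries paired by column number, 790 when only the 6 Mecp2-null libraries were fitted and 959 with no filter.

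In Mecp2-null cultures 21 of 27 rapid immediate early genes rose with KCl and none fell, 23 when adjusted over the list alone, with a median of 2.68 (camera adjusted p = 1.64e-38, and adjusted p = 0.000976 with an estimated correlation). In the other fits adjusted p with an estimated correlation was 0.0311 with library set as a term, 0.507 in high-numbered libraries only and 0.359 with libraries paired, while the median stood at 2.74, 3.07 and 2.74. Arc rose by 2.27 and Egr1 by 1.63. Of the delayed genes 26 of 39 rose, 34 when adjusted over the list alone (camera adjusted p = 7.54e-32, and adjusted p = 0.0556 with an estimated correlation), with Nr4a2 at 4.77, Ptgs2 at 4.32 and Pim1, a kinase gene, at 3.24. Of the MAP kinase feedback regulators 8 rose and 2 fell, 13 and 2 when adjusted over the list alone, with Dusp1 at 3.47 (camera adjusted p = 1.83e-09, and adjusted p = 0.0556 with an estimated correlation). Of the unfolded protein response genes 4 of 19 rose, 5 when adjusted over the list alone, among them Xbp1 at 1.04 and the chaperone gene Hspa5 at 0.80 (camera adjusted p = 3.02e-05, and adjusted p = 0.0556 with an estimated correlation). Of the heat shock genes 4 rose and 1 fell, 5 and 1 when adjusted over the list alone, with Hspa1b at 2.72 and Hspa1a at 1.75 (camera adjusted p = 0.00036, and adjusted p = 0.128 with an estimated correlation). In the glucocorticoid list 6 of 19 rose, and 6 rose and 1 fell when adjusted over the list alone, with Arl4d at 1.57 (camera adjusted p = 8.33e-05, and adjusted p = 0.128 with an estimated correlation). In the cytokine list 3 of 13 rose, also adjusted over the list alone, with Csrnp1 at 3.91 (camera adjusted p = 0.00175, and adjusted p = 0.754 with an estimated correlation).

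Ddx3y rose by 1.84 and Uty by 1.02 in Mecp2-null cultures, again 2 of 6 listed genes, also adjusted over the list alone (camera adjusted p = 0.0118, and adjusted p = 0.194 with an estimated correlation). Cytosolic ribosomal protein genes had 64 of 71 members higher with KCl in Mecp2-null cultures, by a median of 0.08, with none called (camera adjusted p = 0.00212, and adjusted p = 0.938 with an estimated correlation). Sst, a neuropeptide of inhibitory neurons, rose by 1.27 and Crh by 2.62, and lower were the excitatory marker Emx1 at -1.08, the progenitor marker Hes5 at -1.54 and the glutamate receptor gene Grik3 at -0.75. Emx1 and Hes5 ran against most of their lists, as 9 of 15 excitatory and 18 of 20 proliferating and progenitor markers were higher. Of the proliferating markers 6 rose and 1 fell with library set as a term (camera adjusted p = 0.0123, and adjusted p = 0.864 with an estimated correlation). In that fit 12 of 40 histone genes rose (camera adjusted p = 8.48e-05, and adjusted p = 0.723 with an estimated correlation), as did 3 of 18 interferon genes (camera adjusted p = 0.000313, and adjusted p = 0.527 with an estimated correlation) and 3 of 17 microglia markers (camera adjusted p = 0.0177, and adjusted p = 0.189 with an estimated correlation). In the fit of all libraries their lists did not pass in Mecp2-null cultures, with camera adjusted p of 0.201 for inhibitory neurons, 0.165 for genes linked to MeCP2, 0.41 for excitatory neurons and for glutamate receptors, and 0.817 for proliferating cells.

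The genes called with KCl were largely shared. In both genotypes 368 genes rose, where 12.3 would be shared by independent lists, and 497 fell, where 22.5 would be shared, and none went opposite ways. Both lists came from the same fit with the same spread estimated for a gene, so they are not independent. The numbers expected are therefore no test of agreement. Across the 19972 genes, which are not independent replicates, fold changes in the genotypes correlated with r = 0.868 and rho = 0.815, and with r = 0.813 and rho = 0.794 in high-numbered libraries only.

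**Figure D3:**
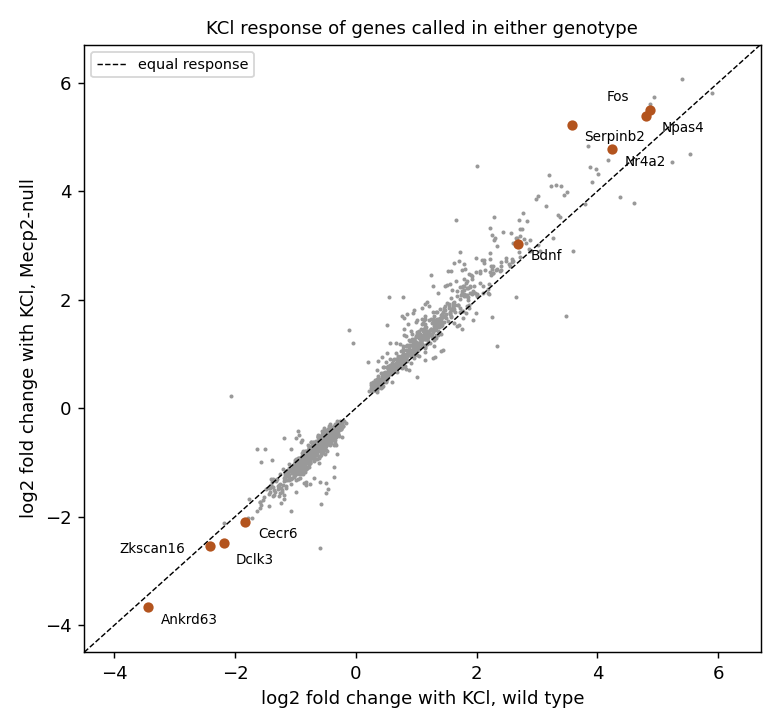
Log2 fold change with KCl in wild-type cultures (horizontal) and in Mecp2-null cultures (vertical) for the 1543 genes called in either genotype, 1 grey point per gene, with named genes in orange and a dashed line where responses are equal. Fos at 4.87 and 5.50 and Npas4 at 4.80 and 5.38 lie above the line.

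Untreated cultures were compared between genotypes to show what MeCP2 loss changes at rest. Mecp2 was lower in Mecp2-null cultures by a log2 fold change of -4.04 (SE 0.22, adjusted p = 0.000102) and was the only gene that edgeR called, with 74 genes at an unadjusted p under 0.05 and 1 gene called by DESeq2. Chance alone would give a share of 0.05 of the 19972 genes, which is far more. This fit counts the difference between library sets as error, with a common coefficient of variation of 0.405. With library set as a term it was 0.109, and 915 genes had an unadjusted p under 0.05. Few calls in the fit of all libraries therefore do not show that genotype changes little, here or in the other genotype comparisons and the interaction. No gene was called when only the 6 untreated libraries were fitted. Irak1 differed by 1.01 (SE 0.45, adjusted p = 1) and by 1.59 in high-numbered libraries only (adjusted p = 4.04e-06). With library set as a term 2 genes were called, Mecp2 and Ttr, the latter at -3.27 (SE 0.35, adjusted p = 0.00583), whose counts lay in 1 low-numbered library per genotype, at 116.5 CPM in wild type and 11.2 CPM in Mecp2-null.

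Shifts of whole lists were found between untreated genotypes, with no member called in the fit of all libraries, over all genes or adjusted over the list alone, except Mecp2 among genes over 100 kb. Adjusted over the list alone with library set as a term, 12 of 20 proliferating markers, 6 histone genes, 3 choroid plexus markers, 1 fibroblast marker and 1 oligodendrocyte precursor marker fell. In that fit 1 gene linked to MeCP2 and 1 gene of the sodium and calcium channels rose. Of all these only Ttr passed over all genes. The largest shift in the fit of all libraries was that of fibroblast and meningeal markers, lower in Mecp2-null cultures in 12 of 13 members by a median of -1.83 (camera adjusted p = 0.0469, and adjusted p = 0.865 with an estimated correlation). Their median was 0.04 in high-numbered libraries only. Choroid plexus markers had a median of -0.81 and did not pass (camera adjusted p = 0.681), against 0.22 in high-numbered libraries only. With library set as a term this list passed downward at a median of -0.70 (camera adjusted p = 2.1e-05, and adjusted p = 0.227 with an estimated correlation). Nuclear genes of oxidative phosphorylation were higher in Mecp2-null cultures in 70 of 74 members, by a median of 0.09 (camera adjusted p = 1.8e-17, and adjusted p = 0.792 with an estimated correlation). Mitochondrially encoded mRNAs were higher in 10 of 11 members, by a median of 0.13 (camera adjusted p = 0.000188, and adjusted p = 0.792 with an estimated correlation). Proliferating and progenitor markers were lower in 20 of 20 members, by a median of -0.71 (camera adjusted p = 0.00172, and adjusted p = 0.865 with an estimated correlation), and histone genes by a median of -0.56 (camera adjusted p = 0.0109, and adjusted p = 0.865 with an estimated correlation). Rapid immediate early genes were lower in 24 of 27 members, by a median of -0.20 (camera adjusted p = 0.0173, and adjusted p = 0.792 with an estimated correlation). Genes over 100 kb passed upward with a median of 0.01 and a mean of -0.03 (camera adjusted p = 0.049, and adjusted p = 0.792 with an estimated correlation). In high-numbered libraries only, the medians were 0.08 for nuclear and 0.11 for mitochondrially encoded genes of oxidative phosphorylation, -0.26 for proliferating markers, 0.03 for histones and -0.10 for rapid immediate early genes. In all 15 lists passed with the preset correlation, and none with an estimated correlation.

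With KCl the genotypes were compared again, which asks how stimulated cultures differ. Mecp2 was lower by -4.31 (SE 0.22, adjusted p = 6.33e-05), the only gene that edgeR called of 96 at an unadjusted p under 0.05. DESeq2 called 2, Mecp2 and the X-linked actin-bundling gene Pls3 (75785654 to 75875182), the latter at -0.69. With library set as a term 4 genes were called, Mecp2, Pls3 at -0.70 (SE 0.08, adjusted p = 0.00538), Ptgs2 at 0.71 (SE 0.08, adjusted p = 0.00743) and Ttr at -3.81, whose difference rests on 1 low-numbered library per genotype. Pls3 averaged 149.8 ± 0.46 CPM in wild-type and 93.2 ± 11.5 CPM in Mecp2-null KCl libraries (SD, n = 3 each). Arc stood at 26.4 ± 4.35 CPM in wild-type and 42.4 ± 4.69 CPM in Mecp2-null KCl libraries (SD, n = 3 each), a difference of 0.68 (SE 0.19, adjusted p = 1).

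As a list, the rapid immediate early genes were higher in Mecp2-null KCl cultures in 23 of 27 members, by a median of 0.36, with none called over all genes or adjusted over the list alone in the fit of all libraries (camera adjusted p = 1.1e-16, and adjusted p = 0.0233 with an estimated correlation). Adjusted over the list alone, 8 rose with library set as a term and 18 in high-numbered libraries only, and none over all genes. The median was 0.34 in high-numbered libraries only. Delayed activity genes were higher in 38 of 39 members, by a median of 0.24 (camera adjusted p = 1.01e-13, and adjusted p = 0.187 with an estimated correlation), and MAP kinase feedback regulators in 15 of 16, by 0.19 (camera adjusted p = 6.43e-06, and adjusted p = 0.187 with an estimated correlation). Nuclear genes of oxidative phosphorylation were higher in 71 of 74 members, by 0.10 (camera adjusted p = 7.7e-22, and adjusted p = 0.187 with an estimated correlation). Proliferating markers were lower in all 20 members, by -0.40 (camera adjusted p = 0.0099, and adjusted p = 0.757 with an estimated correlation). The cytokine list passed upward with a median of -0.07 and a mean of 0.06 (camera adjusted p = 0.026, and adjusted p = 0.757 with an estimated correlation). In high-numbered libraries only, these medians stood at 0.24 for delayed genes, 0.22 for MAP kinase regulators, 0.10 for oxidative phosphorylation, -0.33 for proliferating markers and 0.07 for cytokines. Of 17 lists that passed with the preset correlation, only the rapid immediate early genes passed with an estimated correlation, and they did not with library set as a term (adjusted p = 0.233) or in high-numbered libraries only (adjusted p = 0.503).

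Averaged over both treatments, the genotypes were compared with 6 libraries each. Mecp2 was lower by -4.18 (SE 0.15, adjusted p = 2.8e-06), the only gene that edgeR called of 164 at an unadjusted p under 0.05, and DESeq2 called Mecp2 and Pls3. Irak1 differed by 1.10 (SE 0.32, adjusted p = 1). With library set as a term 8 genes were higher and 17 lower in Mecp2-null cultures. Among the higher were Irak1 at 1.25 (SE 0.18, adjusted p = 0.0315), Ptgs2 at 0.55 (SE 0.07, adjusted p = 0.0108) and Hs6st3, a heparan sulfate sulfotransferase gene, at 0.51. Among the lower were Pls3 at -0.62 (SE 0.05, adjusted p = 0.000395), the matrix gene Fbln2 at -0.80, the retinol binding gene Rbp1 at -0.45, Mki67 at -0.64 and Hist1h2bk at -0.81. Pls3, like Irak1, lies within 5 Mb of Mecp2. Ttr at -3.54 and Lum at -3.56 also fell, both genes with at most 0.101 CPM in any high-numbered library, so these differences rest on 2 low-numbered libraries per genotype. In high-numbered libraries only, 20 genes were higher and 19 lower, with Irak1 at 1.68 and Pls3 at -0.67. These fits took an untreated and a KCl library with neighbouring numbers as independent. With such pairs summed, 3 per genotype, edgeR called Mecp2 alone, and with library set as a term 4 genes, Mecp2, Ttr, Pls3 at -0.63 (SE 0.06, adjusted p = 0.0306) and Ptgs2 at 0.65 (SE 0.06, adjusted p = 0.0296), but not Irak1 at 1.24 (SE 0.23, adjusted p = 0.538).

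Over both treatments, 19 lists passed with the preset correlation and none with an estimated correlation. Nuclear oxidative phosphorylation genes were higher in 71 of 74 members by a median of 0.10 (camera adjusted p = 7.26e-29, and adjusted p = 0.42 with an estimated correlation), and by 0.08 in high-numbered libraries only. Inhibitory neuron markers were higher in 18 of 20 members by a median of 0.17, and by 0.13 in high-numbered libraries only (camera adjusted p = 4.42e-06, and adjusted p = 0.42 with an estimated correlation). Voltage-gated sodium and calcium channels were higher in 23 of 26 members by a median of 0.12, but by a median of 0.00 in high-numbered libraries only (camera adjusted p = 3.3e-05, and adjusted p = 0.683 with an estimated correlation). Histone genes were lower in 38 of 40 members by a median of -0.42, and by -0.01 in high-numbered libraries only (camera adjusted p = 0.0114, and adjusted p = 0.871 with an estimated correlation). Proliferating markers were lower in 20 of 20 members by -0.58, and by -0.30 in high-numbered libraries only (camera adjusted p = 0.000324, and adjusted p = 0.683 with an estimated correlation). Genes often linked to MeCP2 were higher in 25 of 34 members by a median of 0.10 (camera adjusted p = 0.000324, and adjusted p = 0.42 with an estimated correlation). Genes over 100 kb passed upward with a median of 0.01 and a mean of -0.01 (camera adjusted p = 0.00846, and adjusted p = 0.42 with an estimated correlation). Heat shock genes passed upward with a median of 0.05 and a mean of -0.03 (camera adjusted p = 0.026, and adjusted p = 0.42 with an estimated correlation).

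The interaction asked whether the response to KCl differed between genotypes. All 27 rapid immediate early genes had a larger fold change with KCl in Mecp2-null than in wild-type cultures, by a median of 0.49 on the log2 scale (camera adjusted p = 5.58e-20, and adjusted p = 0.0107 with an estimated correlation). Arc responded more by 0.75 (SE 0.27), Egr1 by 0.49 (SE 0.18), Fos by 0.63 (SE 0.34) and Npas4 by 0.59 (SE 0.48), each with an adjusted p = 1. The median was 0.50 with library set as a term (adjusted p = 0.13 with an estimated correlation), 0.50 with libraries paired (adjusted p = 0.328 with an estimated correlation) and 0.37 in high-numbered libraries only (adjusted p = 0.809 with an estimated correlation). Excitatory neuron markers had a median interaction of 0.02 and inhibitory markers of 0.04. Between genotypes, interferon-response genes had a median of -0.443 untreated, with 0 of 18 higher in Mecp2-null cultures (camera adjusted p = 0.681), and of 0.03 with KCl. Their interaction had a median of 0.51 with 18 of 18 higher (camera adjusted p = 0.758). That of histone genes was 0.34 with 36 of 40 higher (camera adjusted p = 0.509). These 2 lists passed in the interaction with library set as a term, at medians of 0.26 (camera adjusted p = 7.18e-17, and adjusted p = 0.13 with an estimated correlation) and 0.18 (camera adjusted p = 4.56e-09, and adjusted p = 0.614 with an estimated correlation). Proliferating markers also passed there, at a median of 0.10 (camera adjusted p = 0.00018, and adjusted p = 0.629 with an estimated correlation). In high-numbered libraries only these 3 medians were -0.01, -0.07 and -0.07.

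No single gene passed the interaction test in edgeR, where 53 genes had an unadjusted p under 0.05, nor in DESeq2, where 36 did. The 5 of lowest p were Prdm12 at 2.29 (SE 0.48), Gm14391 at -0.88, Gm12124 at -2.34, Wfdc1 at -1.01 and Serpinb2 at 1.65, each with an adjusted p = 1. The fit with library set as a term called 0 genes as well, with 189 at an unadjusted p under 0.05, and in high-numbered libraries only 0 with 428. All of these counts are below the share of 0.05 of 19972 genes that chance alone would give. Delayed activity genes responded more in 35 of 39 members, by a median of 0.23 (camera adjusted p = 2.21e-06, and adjusted p = 0.727 with an estimated correlation). MAP kinase feedback regulators responded more in 14 of 16 members, by 0.22 (camera adjusted p = 0.000213, and adjusted p = 0.33 with an estimated correlation), and heat shock genes in 15 of 17, by 0.11, with Hspa1a at 0.81 (camera adjusted p = 0.0013, and adjusted p = 0.33 with an estimated correlation). Within high-numbered libraries the median interactions were 0.28, 0.28 and 0.11 for these 3 lists.

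Scores per library gave tests of the same question. The KCl response score, over 1186 induced and 1902 reduced genes, rose from -0.999 ± 0.142 to 0.552 ± 0.287 in wild-type and from -1.05 ± 0.0745 to 0.717 ± 0.336 in Mecp2-null cultures (SD, n = 3 each). The genotype difference in this rise was 0.213 (exact two-sided permutation p = 0.405 over 400 assignments of labels, smallest possible 0.005). It was 0.221 in low-numbered and 0.208 in high-numbered libraries, and the exact p was 0.0417 over 144 assignments within library sets, a permutation chosen after the data were examined. The early gene score rose from 3.35 ± 0.31 to 5.71 ± 0.0695 in wild-type and from 3.22 ± 0.244 to 6.03 ± 0.0794 in Mecp2-null cultures (SD, n = 3 each). The difference in rise was 0.449 (exact two-sided permutation p = 0.09 over 400 assignments, and 0.0278 over 144 within library sets). These assignments moved libraries with neighbouring numbers apart. Moving whole pairs gave an exact two-sided p = 0.5 for the KCl response score and 0.2 for the early gene score over 20 assignments, and 0.167 for both over 12 within library sets, the smallest p possible there. Benjamini-Hochberg adjustment was not applied to these tests of scores.

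**Figure D4:**
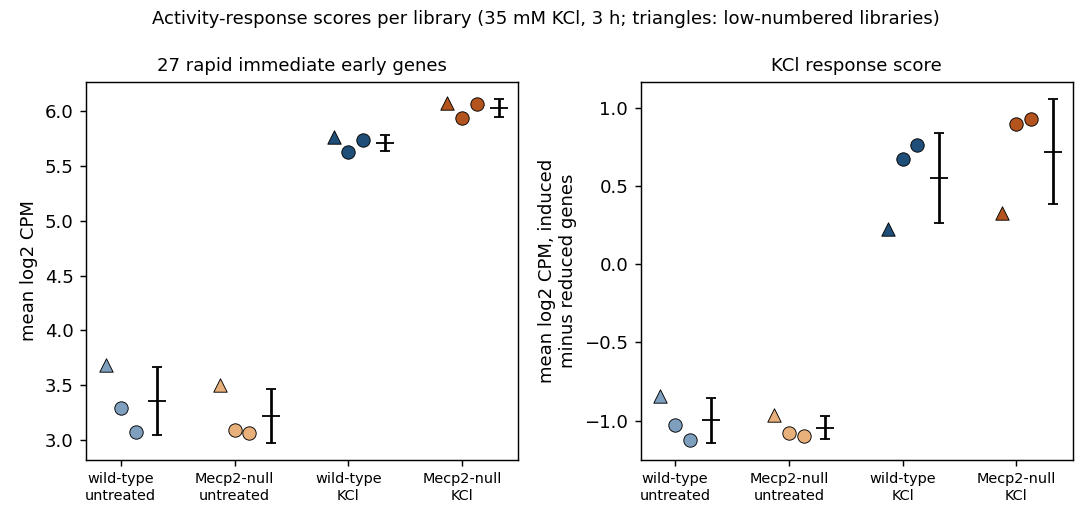
Early gene score (left, mean log2 CPM of 27 rapid immediate early genes) and KCl response score (right, mean log2 CPM of induced minus reduced genes) in each of the 12 libraries by group, with a bar for the mean and SD of 3 libraries. The early gene score was 6.03 ± 0.0794 in Mecp2-null and 5.71 ± 0.0695 in wild-type KCl libraries.

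The long gene score asked whether genes over 100 kb were raised without MeCP2. Among 19450 genes with a length, 2508 were over 100 kb. The difference between their median and that of shorter genes was larger in Mecp2-null than in wild-type libraries by 0.0585 on the log2 scale (exact two-sided permutation p = 0.44). It was 0.14 in low-numbered and 0.0176 in high-numbered libraries, with an exact p = 0.125 within library sets. The value was 0.0239 over genes with a mean of at least 10 CPM, and -0.0118 of these in high-numbered libraries, and 0.1004 with the longest length limit tried. Leaving out a single library moved the long gene shift from 0.0033 (without WT2-WT3_T) to 0.1002 (without MT2-MT3_T).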

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

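Values that stood out in the response to KCl are given first. The list tests and the permutation of labels within treatments were fixed beforehand, and library set and every test that uses it were chosen after the result was seen. Compared between genotypes, the response to KCl was larger in Mecp2-null cultures for rapid immediate early genes (camera adjusted p = 5.58e-20), delayed activity genes (2.21e-06), MAP kinase feedback regulators (0.000213), heat shock genes (0.0013), cytokine and NF-kB genes (0.0035), cytosolic ribosomal protein genes (0.00533) and glucocorticoid responsive genes (0.0345). Only the rapid immediate early genes kept an adjusted p under 0.05 with an estimated correlation, and only in the fit of all libraries. The genotype difference in the rise of the KCl response score had an exact two-sided permutation p = 0.405 in the planned test and 0.0417 when labels were permuted within treatments and library sets. Over genes called with library set as a term the latter was 0.0694, and moving whole pairs of libraries within library sets gave 0.167, the smallest p possible there. Leaving out a single library moved the difference of 0.213 to between 0.0493 (without WT2-WT3_T) and 0.4063 (without MT2-MT3_T).

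Splits of the libraries other than the real groups showed how many genes a wrong grouping would call. The numbers of splits given here include the real grouping as 1 of them. For the KCl response in wild-type cultures 1 of 10 splits reached as many genes as the real 901, with 0 in the highest other, and in Mecp2-null cultures 1 of 10 reached the real 1507, with 0 in the highest other. For the genotype difference in untreated cultures 1 of 10 reached the real count of 1, with 0 in the highest other, and in KCl cultures 1 of 10 reached the real count of 1, with 0 in the highest other. In each of these the splits were too few for a share under 0.05. For the genotype difference over both treatments 11 of 100 drawn splits reached the real count of 1, and the highest other called 4971 genes. That split placed all 4 low-numbered libraries on the same side, so the count points to a structure of the samples, and with library set as a term the real count was 25, the highest other 17 and 1 of 72 splits reached the real count. These splits take libraries with neighbouring numbers as independent, and with such pairs summed the real count with library set as a term was 4. For the interaction the real count was 0, which any split reaches, so the splits cannot test it. The highest other called 4032 genes. It gave the untreated low-numbered libraries the same genotype label and the low-numbered KCl libraries the opposite label. With library set as a term the interaction also called 0 genes.

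The 4 low-numbered libraries stood apart from the other 8 in 13477 genes. The 3 explanations tested here were chosen after the result was seen. Whether these 4 libraries form 1 of the 3 experiments in the labels was not tested, because no library could be tied to an experiment. Library size was set aside, since the totals of all 4 lay inside the range of the others. A lower share of neurons alone would shift all other cell types alike, and 3 of 21 pairs of lists of other cell types had separate interquartile ranges. All 3 held the fibroblast markers (2.393 to 3.661), against astrocyte (0.69 to 2.076), oligodendrocyte (-0.364 to 1.739) and oligodendrocyte precursor markers (-0.165 to 2.101). Lum of the fibroblast list had few counts in high-numbered libraries. As the separation rests on 1 list, a lower share of neurons alone was neither kept nor set aside. More microglia as the source of the interferon genes was not set aside, since the ranges of these lists overlapped by 0.83 (-0.83 as lower minus upper quartile). The microglia range was wide (1.483 to 4.488), and the interferon median of 4.877 lay above it. Such an overlap cannot show the source, which leaves cell composition and an interferon response of other cells open.

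The mean rise of rapid immediate early genes with KCl was larger in Mecp2-null cultures, by 0.449 in the early gene score. The exact two-sided permutation p was 0.09, and 0.2 when whole pairs were moved, and no single gene passed the interaction test. The tests of excitatory neurons and of all induced genes were written down before their values were computed, and that of library set was chosen after the result was seen. The difference had the same sign in both library sets, at 0.42 in high-numbered libraries, with 2 per group, and 0.50 in low-numbered libraries, with 1 per group. So few libraries do not exclude a part played by library set. A larger share of excitatory neurons was tested on levels after KCl, not on the rise, in the fit with library set as a term. It could be neither kept nor excluded, as the marker range and the early gene range overlapped by 0.07. Median genotype differences after KCl were 0.18 for the markers and 0.358 for the early genes. Untreated they were 0.209 for the markers and -0.134 for the early genes. A larger response of all KCl-induced genes may account for it, because the median ratio of the early genes lay 0.121 below the upper quartile of the other induced genes, of which 80.7% responded more in Mecp2-null cultures.

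Irak1, next to Mecp2, was higher in Mecp2-null cultures, and by less in low-numbered libraries, because wild-type levels there were higher. The test of variant DNA was written down before its value was computed, and that of read-through was chosen after the result was seen. DNA of another strain around the targeted gene may alter neighbouring genes, and Pls3 also lies within 5 Mb of Mecp2. With Mecp2, Irak1 and Pls3 left out, 16.2% of the 80 other tested genes within 5 Mb had a genotype p under 0.05. The share was 9.5% of 600 other X-linked genes (one-sided Fisher exact p = 0.0531), which cannot tell. For the difference of Pls3, at -0.62, this stays open as well. Transcription running on from the Mecp2 promoter in proportion to its activity also stays open. The excess of Irak1 per wild-type Mecp2 in low-numbered libraries was 0.413 untreated and 0.574 with KCl of that in high-numbered libraries, but with 1 low-numbered library per group these ratios have no spread. Whether the targeted allele itself raises Irak1 was not tested.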

How the results depend on the processing

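The columns carry no experiment number, so the planned block by experiment was not run, and neither were the alternatives planned for the hippocampus. A replicate block by neighbouring column numbers, chosen after the data were seen and not given by the labels, called 5369 genes for the KCl response in wild-type and 6380 in Mecp2-null cultures and 0 for the interaction. The deviations of paired libraries correlated with r of 0.722 to 0.916, in each pair above the untreated library's r with any other KCl library of its genotype. In high-numbered Mecp2-null pairs the margin was small, at 0.735 against 0.665 and 0.722 against 0.7. The low-numbered pairs could be compared only with high-numbered libraries, so library set alone would give their order. Within high-numbered libraries r was 0.11 in Mecp2-null and 0.393 in wild-type cultures, a hint from the data and not the design. With this block 14 list tests were stronger and 5 weaker, the latter cytokines in wild-type cultures (camera adjusted p = 0.118), sex chromosome genes in wild-type (0.105) and Mecp2-null cultures (0.0879), and glucocorticoid (0.0796) and ribosomal protein genes (0.0721) in the interaction. No list passed with this block and an estimated correlation. For genotype over both treatments, 1 gene was called with paired libraries summed and 4 with paired libraries summed and library set as a term, both also chosen after the data were seen. For the KCl response in wild-type cultures 901 genes were called, 454 with no filter on low counts, 1 with only the groups compared and 1690 with DESeq2. For the KCl response in Mecp2-null cultures 1507 were called, 959 with no filter and 790 with only the groups compared. For the genotype difference in untreated cultures 1 gene was called and 0 with only the groups compared, and DESeq2 called 2 for the genotype difference in KCl cultures and 2 over both treatments. Leaving out each library in turn gave 123 (without WT45_N) to 1355 (without WT2-WT3_T) in wild-type cultures, with 217 without WT39_N, 223 without WT46-WT47_T and 241 without WT40-WT41_T, and 454 (without MT33_N) to 1913 (without MT2-MT3_T) in Mecp2-null cultures, with 481 without MT34-MT35_T, 495 without MT27_N and 505 without MT28-MT29_T. The genotype counts stayed at 1 and the interaction at 0 whichever library was left out. Bdnf lost its call in each genotype without any of 5 of the 6 libraries and Zfp94 without any of the 4 high-numbered ones. Response size ran from 0.0493 (without WT2-WT3_T) to 0.4063 (without MT2-MT3_T) and the long gene shift from 0.0033 to 0.1002 without the same libraries. The next alternatives were chosen after the data were seen. With library set as a term the counts were 4513 and 5378 for KCl in wild-type and Mecp2-null cultures and 2, 4 and 25 for genotype in untreated cultures, in KCl cultures and over both treatments. In high-numbered libraries only they were 6464, 7133, 5, 5 and 39. The 5 in untreated cultures were Mecp2, Irak1, Pls3, Igfbp5 and Tgm1 and the 5 with KCl Mecp2, Irak1, Pls3, Ptgs2 and Igfbp5, chosen after their values were seen. Response size of 0.2127 passed when labels were permuted within library sets (exact two-sided p = 0.0417), not when whole pairs were permuted (0.5, and 0.167 within library sets), and over genes called with library set as a term it was 0.1362, with an exact two-sided p = 0.0694 within library sets. In high-numbered libraries only, lists took the other sign for genotype in untreated cultures, with camera adjusted p of 0.503 for potassium channels, 0.842 for histones, 0.343 for CA1 and CA3 markers and 0.725 for genes over 100 kb, and over both treatments with 0.787 for potassium channels, 0.973 for excitatory markers and 0.787 for CA1 and CA3 markers. In the fit of all libraries, only the rapid immediate early genes passed with both the preset and an estimated correlation. They did so in both KCl responses, between genotypes with KCl and in the interaction. With an estimated correlation 71 list tests lost their pass and 137 stayed the same, most of which had not passed with the preset correlation either. The 2 runs took different correlations, 0.01 in the preset one. Over both treatments in the fit of all libraries, it was estimated at 0.341 for nuclear oxidative phosphorylation genes, 0.8 for sodium and calcium channels and 0.916 for histones. It was 0.0826 for rapid immediate early genes and 0.0187 for dentate granule cell markers. Why members of a list moved together was not tested. In simulated data 24, 54, 88 and 92% of genes changed by 1.5, 2, 4 and 8 times were called over both treatments, and 92, 100, 100 and 100% with library set as a term, where 6 libraries per genotype are compared. In untreated cultures 4% of genes changed by 1.5 times were called, and 64% with library set as a term. Among 19772 unchanged genes, 0 were called over both treatments, 0 untreated and 1 with KCl, against 6, 6 and 9 with library set as a term. The simulated counts were drawn from the fit with that term and took libraries as independent, which favours that fit. They show which planted changes each fit could call, not whether such differences exist in the cultures. Depth was alike in all libraries, so it does not account for the few counts of Ttr and Lum in high-numbered libraries. Genotype differences of these genes cannot be judged there.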

Other observations

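In Mecp2-null KCl libraries the early gene score was higher in each of 3 than in each of 3 wild-type KCl libraries (5.936 to 6.078 against 5.632 to 5.763). The difference was 0.317 with an exact two-sided permutation p = 0.1, the smallest that 3 against 3 libraries allow, and untreated it was -0.133 (p = 0.6). Further libraries of each genotype with KCl, with library number balanced over groups, would test it.

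Ddx3y went from 85.0 ± 4.30 to 282 ± 93.5 CPM with KCl in wild-type and from 84.0 ± 4.28 to 301 ± 105 CPM in Mecp2-null cultures (SD, n = 3 each). All cultures came from males, and reads along the gene would show whether the rise lies in its mRNA or in transcription past its end.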
